A study of Canis lupus familiaris with 15 samples.

How the data were processed

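Total RNA from 3 canine mammary tumour cell lines near confluence was isolated with a column kit, amplified by T7 transcription with aminoallyl nucleotides and coupled to Cy3 or Cy5, per the labels' protocols. Each of 15 cDNA arrays was hybridised with a pair of lines, 5 arrays per pair, with dyes swapped within pairs. The deposited value table holds log2 ratios of the 2 dyes that the authors had normalized and log transformed, per the series design text. The normalization method and the log base are not given in the sources used here. The base was read as 2 because the largest absolute value, 12.43, is a 5511-fold ratio on a log2 scale, whereas a natural log would need 249732-fold, beyond the 65536-fold range of a 16-bit scan. Array medians as deposited lay close to 0, from -0.00671 to 0.0133, so the values appear centred. The numerator is not stated and was read as Cy5, the first channel in the labels, so the direction of every ratio is likely and not settled. Intensities and background were not used here, so the depth behind a ratio is unknown, and the number of arrays limits the precision.

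The table had 22176 probes and 2 missing values. The platform annotation gave 1 symbol for 7694 probes, several for 0 and none for 14482, which are unnamed here. Symbols were updated through Entrez identifiers in the RefSeq gene table of assembly UU_Cfam_GSD_1.0 for 7340 probes, and 354 kept the platform symbol. Each array was turned to the order of its pair by its dyes, and probes of a gene were averaged per array. This gave 5246 genes, 3627 with 1 probe, 1619 with more and at most 27. Probes of a gene were called in opposite directions for 4 genes in P114 against CMT-U335 (ANKHD1, ATP5IF1, ITGA6 and TIMP3), for 0 in P114 against CMT-U229 and for 1 in CMT-U229 against CMT-U335 (C2). A gene needed a value on at least 3 of the 5 arrays. No deposited column belonged to another series.

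Each pair was fitted by itself with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, testing the mean log2 ratio of 5 arrays against 0, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The study's own design tested each pair by itself with SAM, and limma took its place. A gene was set apart in a line when it was called in both of the line's pairs in the same direction. Loop closure was tested in a fit over all 15 arrays as the direct ratio minus the sum of the indirect ones. Of 35 lists of genes, 31 had at least 5 measured members and were tested with camera (preset correlation 0.01), two-sided, with adjustment over 93 tests. With an estimated correlation, camera used the few residual degrees of freedom of 5 arrays instead of ones set by the number of genes. The lists for cartilage (2 measured), Notch signalling (4), mammary hormone receptors and milk (4) and adipocytes (4) were too short for it. Counts of list members are those called over all genes. For the lists not called by camera, the counts adjusted over the list alone differed from these by at most 3 genes in either direction.

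The samples' groups, the designs, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each pair, the 8 genes with the largest mean ratio in each direction among called genes with the same sign on at least 4 arrays and on every array measured. It also took up to 4 called members of each list, or 2 members as values where none was called, the 5 leading genes in each direction for each line, and MET, ERBB2, EGFR and VIM. Alternatives were array medians at 0, scale normalization between arrays, stricter and looser filters on missing values, a dye term, fits over all 15 arrays, a loop fit, the replicate number as a block, other thresholds, a SAM-type test, each probe by itself, fry or an estimated correlation for lists, the turned direction, and each array left out. The closing section gives their effect. Apparent dye swaps were looked for after the data were seen, among all 15 ways to split 5 arrays into 2 couples and a single array. The way with the smallest median share of a gene's variation within couples was taken, over genes with an SD above 0.5 and a dye effect under 0.1 in the other pairs, and couples were averaged before the fit of 3 values.

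The tests were run on simulated arrays for 5245 genes with known changes. At log2 changes of 0.5, 1 and 2, limma recovered 54.8%, 87.9% and 98.4% of changed genes for P114 against CMT-U335, where 9 of 167 calls were false. For P114 against CMT-U229 it recovered 56.0%, 93.8% and 100% with 3 of 166 calls false, and for CMT-U229 against CMT-U335 46.1%, 85.7% and 96.7% with 9 of 157 false. In each pair the changed list was called and 0 unchanged lists were. The simulated noise was drawn independently for each gene and array, so it held no dye swaps of the same RNA and no correlation between genes. These shares therefore do not cover the false calls that either could cause in the real arrays. A gene-specific dye effect was found for 616 of 5245 genes (11.7%) in a fit over 15 arrays. Among called genes its share was 5.39%, 3.13% and 4.18% in P114 against CMT-U335, P114 against CMT-U229 and CMT-U229 against CMT-U335. A dye effect widens the spread between arrays of opposite dye order and so makes a call less likely. A lower share among called genes is therefore built in and does not show that the calls are free of dye effects. Dye orders were 3 against 2 in each pair, so a dye effect cancelled in part. Medians of 48 successive blocks of probes varied less than those of shuffled probes on 15 of 15 arrays.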

Results

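Gene expression was compared between 3 canine mammary tumour cell lines on 15 cDNA arrays with 2 dyes each. P114 came from an anaplastic carcinoma, CMT-U335 from an osteosarcoma of the mammary gland and CMT-U229 from a benign mixed tumour. Each array carried RNA from a pair of lines, and the 3 pairs had 5 arrays each. Within each pair the dyes were swapped on 2 or 3 of the arrays, so the lines formed a closed loop. The labels call the 5 arrays of a pair biological replicates, whereas the series design speaks of dye swaps with at least 1 biological replicate per pair. Some arrays may therefore be technical repeats, and p-values measure the spread between arrays. Among genes that varied and had little dye effect, replicates 1 and 3 lay close together in P114 against CMT-U229, as did 2 and 5. In CMT-U229 against CMT-U335 replicates 2 and 3 did, as did 4 and 5. Each of these couples had opposite dyes, as swaps of the same RNA would have. In these genes, 210 and 137 in turn, a median share of 0.0486 and 0.105 of a gene's variation lay within couples, where the lowest of 100 shuffles gave 0.412 and 0.388. Over all probes, dye effects included, the couples were not the best correlated, at 0.22 and 0.17 and at 0.34 and 0.19 once turned to the same direction. Arrays of the same dye order reached 0.32 and 0.50 in these pairs. In P114 against CMT-U335 the couples were unclear (0.411 for 1 with 3 and 4 with 5, 0.437 for 1 with 3 and 2 with 4, lowest shuffle 0.446). If the couples are swaps, a pair holds 3 separate samples, and the p-values and counts over 5 arrays given here are too favourable, as the SE of single genes can be. The median SE over genes went from 0.0969 to 0.0959 in P114 against CMT-U335 when couples were averaged. It went from 0.101 to 0.09 in P114 against CMT-U229 and from 0.0929 to 0.106 in CMT-U229 against CMT-U335. A fit of 3 values also has fewer degrees of freedom. Counts with the apparent swaps averaged, an alternative chosen after seeing the data, stand beside those over 5 arrays. The deposited log ratios covered 22176 probes, of which 7694 carried a gene symbol and gave 5246 genes. No spot intensities were used here, so distance from background is unknown for every gene, and the number of arrays limits the precision.

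All ratios below are mean log2 ratios over 5 arrays, with the standard error from limma, and a gene was called when its Benjamini-Hochberg adjusted p lay under 0.05. The direction of each ratio is likely and not settled. It rests on reading the deposited values as Cy5 over Cy3, because Cy5 is the first channel in the labels. Arrays of opposite dye order in a pair ran opposite, with correlations over probes from -0.35 to -0.23 for P114 against CMT-U335 and from -0.22 to -0.09 for P114 against CMT-U229. For CMT-U229 against CMT-U335 they ranged from -0.34 to 0.0002. Arrays of the same dye order correlated at 0.29 to 0.42, 0.20 to 0.32 and 0.24 to 0.50 in the same order of pairs. If the deposited values were Cy3 over Cy5, every higher gene below would be lower and the counts in each direction would change places. The log base is also not stated and was read as 2.

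The carcinoma line P114 was first set against the osteosarcoma line CMT-U335. The most strongly raised gene was SPP1, which encodes the secreted bone matrix protein osteopontin, 17.4-fold higher in P114 (log2 4.12 ± 0.18 SE, n = 5, adjusted p = 2.47e-05, limma). Genes of the epithelial surface and skeleton came next: EPCAM, an epithelial adhesion molecule, was 11.7-fold higher (3.55 ± 0.15) and KRT18, a keratin of simple epithelia, 11.1-fold higher (3.48 ± 0.19). MT2A, a metal-binding metallothionein, was 9.33-fold higher, and CDKN1A, an inhibitor of cyclin-dependent kinases, 8.74-fold higher. The fatty acid carrier FABP3 (2.94 ± 0.42) and the membrane proteins TMEFF2 (2.91 ± 0.11) and STEAP1 (2.88 ± 0.15) completed the 8 largest ratios. In the opposite direction, PROS1, the anticoagulant protein S, was 10.2-fold lower in P114 (-3.36 ± 0.16), and CTSK, the collagen-degrading protease cathepsin K, was 9.79-fold lower (-3.29 ± 0.25). ALDH1L2, a mitochondrial folate enzyme, stood at -2.93 ± 0.15 and the membrane glycoprotein gene SGCE at -2.61 ± 0.11. The protease inhibitor TFPI2 was at -2.45 ± 0.21. The actin-binding proteins CALD1 and PLS3 were at -2.27 ± 0.0928 and -2.25 ± 0.17, and the spectrin gene SPTAN1 at -2.46 ± 0.44.

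In the gene lists for this pair, 5 of 9 measured epithelial markers rose in P114 and 1 fell, among them KRT8 at 2.46 ± 0.20 and the tight junction gene TJP1 at -0.35 ± 0.0816 (camera, adjusted p = 0.00457; adjusted p = 0.703 with an estimated correlation). Of 10 immediate early and stress response genes 5 rose and none fell (adjusted p = 0.00189, and adjusted p = 0.703 with an estimated correlation). They included the transcription factor FOS at 1.82 ± 0.26 and the phosphatase DUSP6 at 1.68 ± 0.15. This list also marks handling of the cells, so in any pair its shift need not be a trait of the lines. Of 13 genes for folding in the endoplasmic reticulum 3 rose, namely the disulphide isomerase PDIA3 (0.99 ± 0.13), XBP1 (0.83 ± 0.13) and HSPA5 (0.66 ± 0.14), with adjusted p = 0.00299 and adjusted p = 0.703 with an estimated correlation. Of 54 ribosomal protein genes 14 rose and 1 fell, with RPL8 at 1.83 ± 0.16, RPL30 at 1.23 ± 0.0777 and RPL24 at -0.46 ± 0.14 (camera, adjusted p = 0.00189, and adjusted p = 0.797 with an estimated correlation). Fry did not call the ribosomal list (adjusted p = 0.261), and its median lay above 0 on 4 arrays and below 0 on 1. Of 24 genes for initiation and elongation of translation 6 rose and 2 fell, led by EIF3E at 1.55 ± 0.0945, EEF1D at 1.53 ± 0.19 and EIF3H, which was 2.83-fold higher (adjusted p = 0.0437; adjusted p = 0.797 with an estimated correlation). RPL8, RPL30, EIF3E, EEF1D and EIF3H all lie on chromosome 13 in the RefSeq table, and without members from that chromosome the translation list was no longer called (adjusted p = 0.339).

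Mitosis genes were lower in P114 than in CMT-U335, with 6 of 11 fallen and none raised. Not all fell evenly: on single arrays CCNB2 ranged from -1.3 to -0.289 and BIRC5 from -1.27 to -0.0658, both weakest in replicate 4. FOXM1, a transcription factor of dividing cells, was at -1.68 ± 0.0821 and the spindle checkpoint gene BUB3 at -0.99 ± 0.10 (camera, adjusted p = 0.00457; adjusted p = 0.703 with an estimated correlation). Of 19 cytosolic and mitochondrial chaperones 8 fell and none rose, among them the chaperonin subunit CCT2 (-1.34 ± 0.0874) and the immunophilin FKBP5 (-1.05 ± 0.13), with adjusted p = 0.00457 and adjusted p = 0.797 with an estimated correlation. Of 23 RNA splicing genes 7 fell and none rose, among them HNRNPA2B1 at -0.68 ± 0.0966 and SNRPB2 at -0.58 ± 0.11 (adjusted p = 0.0421; adjusted p = 0.703 with an estimated correlation). The list of DNA replication missed the threshold (adjusted p = 0.0703), although 4 of its 16 genes fell, with GMNN at -1.02 ± 0.23 and RFC3 at -0.77 ± 0.0833. The proteasome missed it as well (adjusted p = 0.0584), with 7 of 22 genes fallen and 2 raised, and PSMC6 stood at -0.84 ± 0.12. So did oxidative phosphorylation and the citric acid cycle (adjusted p = 0.0564), where 10 of 31 genes fell and 3 rose: NDUFV2 and NDUFB3 of respiratory complex I (2.38 ± 0.14 and 1.73 ± 0.14) and CYC1 (1.44 ± 0.15).

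The remaining lists of this pair were not called by camera. In the extracellular matrix list 5 of 17 rose and 5 fell (adjusted p = 0.395), with the fibronectin gene FN1 at 1.19 ± 0.19 and the type I collagen gene COL1A2 at -1.39 ± 0.14. In the osteoblast and bone list SPP1 and SPARC rose, COL1A2 fell and 3 others were not called (adjusted p = 0.232). Of 8 matrix proteases and inhibitors 2 rose and 2 fell (adjusted p = 0.888), and the protease inhibitor TIMP1 was at 1.30 ± 0.15. Of 7 mesenchymal markers 2 fell, ZEB1 at -0.91 ± 0.13 and FBLN2 at -0.84 ± 0.14 (adjusted p = 0.232). Of 13 basal and myoepithelial markers 2 rose and 2 fell (adjusted p = 0.431). Of 6 cell cycle inhibitors and p53 targets 4 rose and 1 fell (adjusted p = 0.0703), with CCNG1 at 1.37 ± 0.13 beside CDKN1A. Receptor tyrosine kinases and growth factors had 3 raised and 1 fallen of 13 (adjusted p = 0.0703), including the insulin-like growth factor binding protein gene IGFBP7 at 2.59 ± 0.15 and VEGFA at 0.73 ± 0.0769. In cholesterol synthesis the squalene synthase gene FDFT1 rose (2.16 ± 0.0955), whereas SQLE (-1.17 ± 0.12) and 2 others of the 9 fell (adjusted p = 0.261). In Wnt signalling 3 of 13 rose, with CTNNB1, which encodes beta-catenin, at 1.97 ± 0.21 and DKK3 at 1.18 ± 0.0757 (adjusted p = 0.232).

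Glutathione and antioxidant enzymes had 2 raised and 6 fallen of 21 (adjusted p = 0.326), with the quinone reductase NQO1 at 1.58 ± 0.16 and catalase, CAT, at -1.39 ± 0.14. In the interferon and antigen presentation list 2 of 9 rose and 1 fell (adjusted p = 0.533), and the antiviral gene OAS2 was at 2.14 ± 0.20. Actin and adhesion genes had 3 raised and 6 fallen of 23 (adjusted p = 0.869), with the membrane linker EZR at 1.47 ± 0.0707 and the myosin light chain MYL9 at -1.05 ± 0.14. Of 16 hypoxia genes 3 rose and 4 fell (adjusted p = 0.789), of 16 glycolysis genes 3 rose and 1 fell (adjusted p = 0.915), and of 11 genes for TGF-beta and BMP signals 1 rose and 1 fell (adjusted p = 0.725). Of 9 tumour suppressors and oncogenes 1 rose and 3 fell (adjusted p = 0.485), with BCL2 at -0.87 ± 0.19. None of 5 inflammation genes was called (adjusted p = 0.521). Lists of markers of other cell types were not called: 1 of 12 leukocyte markers rose (adjusted p = 0.257), none of 7 endothelial markers was called (adjusted p = 0.893) and 2 of 17 muscle markers fell (adjusted p = 0.915).

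Across all genes, limma called 1169 of 5246 (22.3%) between P114 and CMT-U335, 414 higher and 755 lower in P114. Among them 195 differed at least 2-fold, 86 higher and 109 lower. On all 5 arrays 1131 of the called genes had the same sign. With the apparent dye swaps averaged 839 genes were called. Each of the 16 sign patterns of the 5 arrays was also tested, and the highest count of genes from any other pattern was 0, whereas another pattern gave 10 lists against the 8 called here. Adjusted over the list alone, 16 ribosomal genes rose and 2 fell, 6 immediate early, 8 folding and 5 epithelial genes rose (1 epithelial gene fell), 7 translation genes rose and 2 fell, and 7 mitosis genes, 9 chaperones and 8 splicing genes fell. With an estimated correlation none of the lists was called, and the smallest unadjusted camera p of any list was 0.0145 (immediate early genes). That version rests on the few residual degrees of freedom of 5 arrays. It has little power after adjustment, so a lost call does not by itself show correlation between genes. Of 116 called values of named genes, 21 lost the call when some array was left out, including BIRC5, TJP1, GMNN, RPL24 and SPARC. Of these, RPL24 and SPARC also lost it with a dye term. With the swaps averaged 20 lost it, including SPTAN1, RPL24 and SPARC. The splicing list lost its call without replicate 1 or 2, with scale normalization and with the replicate number as a block (camera, adjusted p = 0.0851). The translation list lost it without replicate 1, 2, 3 or 4, with scale normalization and with the swaps averaged (adjusted p = 0.0504).

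**Figure D1:**
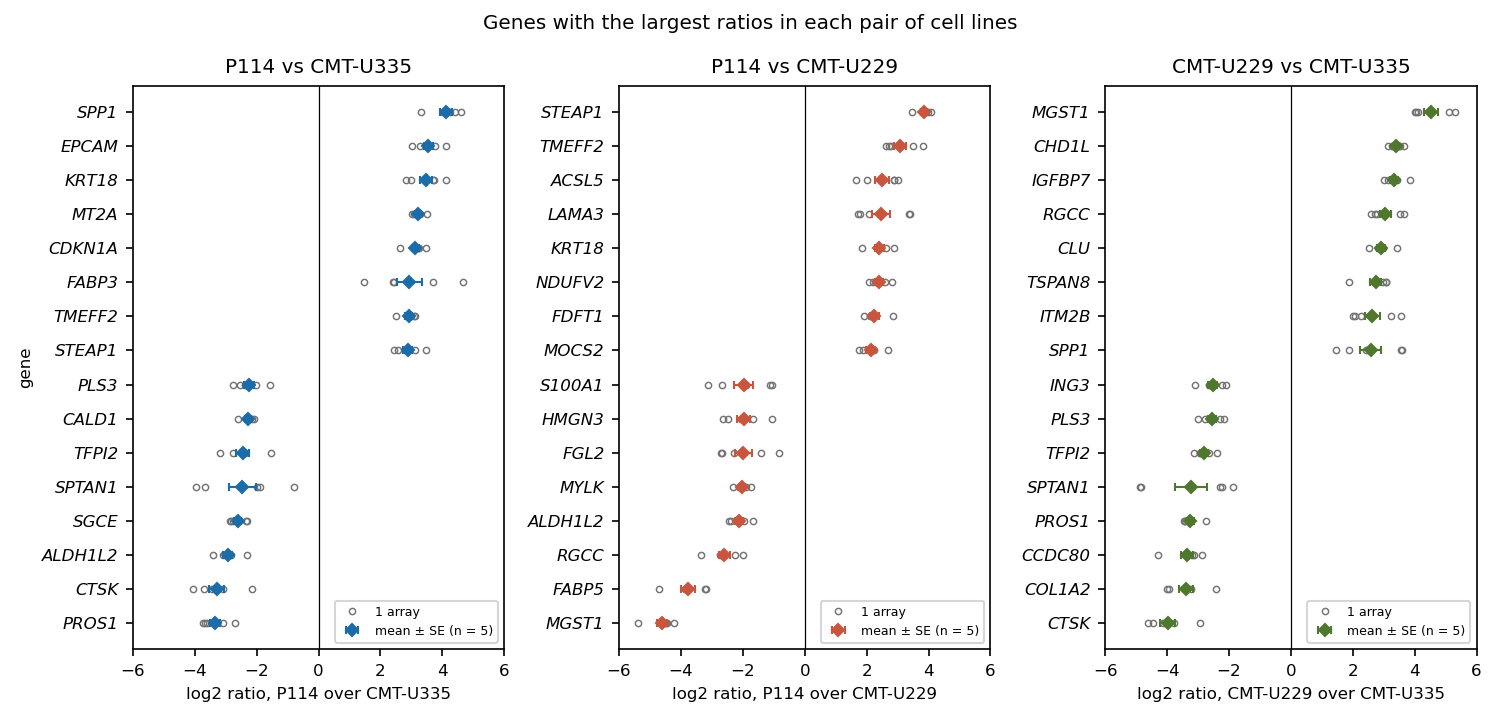
Mean log2 ratio of the 8 genes with the largest ratios in each direction, for each pair of lines (diamonds, mean ± SE over 5 arrays), with the 5 single arrays as open circles. SPP1 leads in P114 over CMT-U335 (4.12), STEAP1 in P114 over CMT-U229 (3.86) and MGST1 in CMT-U229 over CMT-U335 (4.52). Every single array of the genes shown lies on the side of its mean, because the rule that chose them required it.

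P114 was next set against CMT-U229, the line of the benign mixed tumour. The largest ratio belonged to MGST1, a membrane-bound glutathione transferase, which was 24.4-fold lower in P114 (-4.61 ± 0.17 SE, n = 5, adjusted p = 4.03e-05, limma). FABP5, a carrier of fatty acids, was 13.6-fold lower (-3.76 ± 0.22). RGCC was at -2.59 ± 0.19, ALDH1L2 at -2.12 ± 0.12 and MYLK, the myosin light chain kinase of contractile cells, at -2.03 ± 0.10. FGL2, the chromatin protein HMGN3 and the calcium-binding S100A1 followed at -1.98 ± 0.28, -1.98 ± 0.22 and -1.97 ± 0.31. Higher in P114 were STEAP1, 14.5-fold (3.86 ± 0.10), and TMEFF2, 8.50-fold (3.09 ± 0.19). The fatty acid activating enzyme ACSL5 (2.49 ± 0.22), the laminin chain LAMA3 (2.47 ± 0.29), KRT18 (2.41 ± 0.14), NDUFV2 (2.40 ± 0.12), FDFT1 (2.25 ± 0.14) and MOCS2 (2.13 ± 0.14) completed the group.

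Of 17 extracellular matrix genes 7 rose in P114 over CMT-U229 and 1 fell. COL1A2 stood at 2.07 ± 0.30, the matrix glycoprotein SPARC at 1.33 ± 0.21, LAMB1 at 1.05 ± 0.12 and EFEMP1 at -1.71 ± 0.17. The median of the list lay above 0 on 4 arrays and below 0 on 1. Fry did not call the list (adjusted p = 0.0775), whereas camera did (adjusted p = 0.00299, and adjusted p = 0.797 with an estimated correlation). Of 8 matrix proteases and inhibitors 3 rose, namely TIMP1 at 1.22 ± 0.19, the sheddase ADAM10 at 0.75 ± 0.0906 and CTSK at 0.64 ± 0.0770 (adjusted p = 0.0150; adjusted p = 0.703 with an estimated correlation). Of 7 mesenchymal markers 2 rose, S100A4 at 1.54 ± 0.0842 and the proteoglycan DCN at 0.90 ± 0.21 (adjusted p = 0.0252; adjusted p = 0.703 with an estimated correlation). Of 9 epithelial markers 2 rose, KRT18 and EPCAM, the latter at 1.80 ± 0.0988 (adjusted p = 0.00624; adjusted p = 0.703 with an estimated correlation). Of 10 immediate early genes 1 was called, DUSP1 at 1.34 ± 0.31 with adjusted p = 0.0468 in limma (camera for the list, adjusted p = 0.00457; adjusted p = 0.703 with an estimated correlation). Of 21 glutathione and antioxidant enzymes 5 fell and none rose, among them MGST1, CAT at -0.81 ± 0.12, GSTA4 at -0.72 ± 0.0739 and SOD1 at -0.65 ± 0.14 (adjusted p = 0.0383; adjusted p = 0.797 with an estimated correlation). That call was lost with a dye term, with scale normalization, without replicate 5 and with the apparent dye swaps averaged (adjusted p = 0.104).

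The other lists of this pair were not called. In the osteoblast and bone list COL1A2 and SPARC rose among 6 measured (adjusted p = 0.0703). Basal and myoepithelial markers had 2 raised, LAMA3 and CAV1 (1.22 ± 0.0729), and 2 fallen, MYLK and TPM2 (-0.75 ± 0.11), of 13 (adjusted p = 0.888). Of 6 cell cycle inhibitors CDKN1A (1.81 ± 0.32) and CCNG1 (0.57 ± 0.0992) rose and CDKN2C (-1.22 ± 0.22) fell (adjusted p = 0.350). No gene was called among 11 of mitosis (adjusted p = 0.288), 16 of DNA replication (adjusted p = 0.0684), 13 of folding in the endoplasmic reticulum (adjusted p = 0.372), 19 chaperones (adjusted p = 0.462), 24 of translation (adjusted p = 0.431), 5 of inflammation (adjusted p = 0.917) or 7 endothelial markers (adjusted p = 0.732). The medians of the mitosis and replication lists each lay below 0 on 4 arrays and above 0 on 1. The replication genes PCNA and RFC3 were above 0 in replicate 4 alone (0.336 and 0.653). Of 54 ribosomal protein genes RPS20 rose (0.60 ± 0.12) and RPS27A fell (-0.47 ± 0.0891), with adjusted p = 0.0802. NDUFV2 and NDUFB3 (2.12 ± 0.18) rose among 31 genes of oxidative phosphorylation (adjusted p = 0.112), FDFT1 among 9 of cholesterol synthesis (adjusted p = 0.0703), and PGK1 (0.74 ± 0.0882) with GPI (0.45 ± 0.10) among 16 of glycolysis (adjusted p = 0.326). In Wnt signalling CTNNB1 rose (1.53 ± 0.29) and DKK3 fell (-0.51 ± 0.11) among 13 (adjusted p = 0.462).

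B2M, the light chain of the major histocompatibility complex class I molecule, fell (-1.96 ± 0.0754) and was the sole member called among 9 genes of interferon response and antigen presentation (adjusted p = 0.120). P4HA2, a collagen prolyl hydroxylase, rose 2.30-fold with 1 other of 16 hypoxia genes (adjusted p = 0.562), and IGFBP6 (1.01 ± 0.11) rose among 13 growth factor genes (adjusted p = 0.229). HNRNPR (-0.89 ± 0.14) and SRSF10 (-0.41 ± 0.0837) fell among 23 splicing genes (adjusted p = 0.0684), and PSMD11 (-0.40 ± 0.0869) among 22 of the proteasome (adjusted p = 0.367). Actin and adhesion genes had 1 raised and 2 fallen of 23 (adjusted p = 0.0525), TGF-beta and BMP signalling 1 raised of 11 (adjusted p = 0.820) and the tumour suppressors and oncogenes 1 raised of 9 (adjusted p = 0.986). Among markers of other cell types, 1 of 12 leukocyte markers rose, CD14 at 0.50 ± 0.0676 (adjusted p = 0.756), and 1 of 17 muscle markers, ENO3 at 0.62 ± 0.13 (adjusted p = 0.350).

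Limma called 383 of 5246 genes (7.30%) between P114 and CMT-U229, 174 higher and 209 lower in P114, and 93 of them differed at least 2-fold, 52 higher and 41 lower. The same sign held on all 5 arrays for 382. Averaging the apparent dye swaps left 79 called genes, and other ways to couple the arrays left 156 to 414. No other sign pattern of the arrays gave a called gene, whereas another pattern gave 10 lists against the 6 called here. Adjusted over the list alone, 8 matrix genes rose and 3 fell, 4 proteases and inhibitors, 3 mesenchymal, 2 epithelial and 2 immediate early genes rose, and 1 antioxidant enzyme rose and 8 fell. The count rested on each of several arrays, falling to 202, 224, 235 and 223 genes without replicate 1, 2, 3 or 5. Of 60 called values of named genes, 17 lost the call when some array was left out, including CDKN1A, CDKN2C, CCNG1, CTNNB1, DKK3, DCN, DUSP1, SOD1, GPI, RPS20, RPS27A, SRSF10, PSMD11 and ENO3. CTNNB1, DCN, DKK3, DUSP1, SOD1, GPI and PSMD11 also lost it with a dye term. With the swaps averaged 37 lost it, these among them, and also LAMA3, FGL2, HMGN3, S100A1, COL1A2, SPARC, LAMB1, EFEMP1, TIMP1, ADAM10, CTSK, CAT, TPM2, HNRNPR, IGFBP6 and CD14.

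CMT-U229 and CMT-U335 made up the last pair. MGST1 was 22.9-fold higher in CMT-U229 (4.52 ± 0.22 SE, n = 5, adjusted p = 7.81e-05, limma). CHD1L, a chromatin remodeller, was 10.6-fold higher (3.40 ± 0.0906) and IGFBP7 10.1-fold higher (3.34 ± 0.13). RGCC (3.05 ± 0.18), the secreted chaperone clusterin, CLU (2.92 ± 0.12), the tetraspanin TSPAN8 (2.73 ± 0.18), ITM2B (2.63 ± 0.25) and SPP1 (2.58 ± 0.34) followed. Genes lower in CMT-U229 were led by CTSK, 15.8-fold (-3.98 ± 0.23), COL1A2, 10.5-fold (-3.39 ± 0.22), and CCDC80, 10.3-fold (-3.36 ± 0.19). PROS1 was at -3.26 ± 0.12, SPTAN1 at -3.22 ± 0.51, TFPI2 at -2.81 ± 0.12, PLS3 at -2.55 ± 0.13 and ING3, a component of histone acetyltransferase complexes, at -2.52 ± 0.14.

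Genes for folding in the endoplasmic reticulum were higher in CMT-U229 than in CMT-U335, with 6 of 13 raised and none fallen. They included PDIA3 at 1.28 ± 0.13, the chaperone HSPA5 at 0.97 ± 0.20 and calreticulin, CALR, at 0.78 ± 0.12 (camera, adjusted p = 0.00189; adjusted p = 0.703 with an estimated correlation). Mesenchymal markers were lower, with 4 of 7 fallen: S100A4 (-1.58 ± 0.19), FBLN2 (-1.47 ± 0.14), DCN (-0.81 ± 0.11) and ZEB1 (-0.57 ± 0.0842), with adjusted p = 0.00189 and adjusted p = 0.703 with an estimated correlation. Of 54 ribosomal protein genes 14 rose and 2 fell, with RPL8 at 1.71 ± 0.25, RPS27A at 1.36 ± 0.14, RPL7 at 1.32 ± 0.11 and RPL32 at -0.53 ± 0.12 (adjusted p = 0.00359; adjusted p = 0.797 with an estimated correlation). Of 31 genes of oxidative phosphorylation and the citric acid cycle 3 rose and 6 fell, led by NDUFB5 (-1.16 ± 0.11) and SDHB (-0.79 ± 0.17), while CYC1 was at 0.93 ± 0.17 (adjusted p = 0.0118; adjusted p = 0.797 with an estimated correlation). Of 19 chaperones 1 rose and 6 fell, with CCT2 at -1.18 ± 0.16 and FKBP5 at -0.97 ± 0.14 (adjusted p = 0.0379; adjusted p = 0.797 with an estimated correlation).

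Several lists missed the threshold in this pair. Epithelial markers had 3 raised of 9, KRT8 at 2.56 ± 0.23, EPCAM at 1.78 ± 0.14 and KRT18 at 0.79 ± 0.0729 (adjusted p = 0.0703). Mitosis genes had 3 fallen of 11, with FOXM1 at -1.30 ± 0.15 (adjusted p = 0.0574), and 7 of 24 translation genes rose and 1 fell, with EIF3E at 1.38 ± 0.0813 and EIF3H at 1.33 ± 0.0896 (adjusted p = 0.0622). Immediate early genes had 3 raised of 10, with DUSP6 at 1.30 ± 0.18 (adjusted p = 0.0703), and cell cycle inhibitors 2 raised of 6, CDKN1A at 1.64 ± 0.31 and CCNG1 at 1.02 ± 0.0920 (adjusted p = 0.0782). Of 9 cholesterol synthesis genes 4 fell, including MSMO1 (-1.27 ± 0.31) and SQLE (-1.15 ± 0.25), with adjusted p = 0.0730. Actin and adhesion genes had 2 raised and 6 fallen of 23, with the integrin chain ITGB5 at -1.26 ± 0.14 and TPM4 at -1.22 ± 0.22 (adjusted p = 0.0782). Extracellular matrix genes had 4 raised and 4 fallen of 17 (adjusted p = 0.395), among the latter the basement membrane collagens COL4A2 (-1.98 ± 0.0937) and COL4A1 (-1.43 ± 0.16). Matrix proteases and inhibitors had 1 raised and 3 fallen of 8, with ADAM10 at -0.97 ± 0.11 (adjusted p = 0.401), and osteoblast and bone genes 1 raised and 1 fallen of 6, SPP1 and COL1A2 (adjusted p = 0.986).

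Basal and myoepithelial markers had 2 raised and 4 fallen of 13 (adjusted p = 0.803), with MYLK at 2.22 ± 0.0732 and LAMA3 2.30-fold lower. Glutathione and antioxidant enzymes had 5 raised of 21 (adjusted p = 0.367), including MGST1 and NQO1 at 1.49 ± 0.22. In Wnt signalling 3 of 13 rose and 1 fell (adjusted p = 0.735), with DKK3 at 1.64 ± 0.0858, and in TGF-beta and BMP signalling 2 of 11 rose and 1 fell (adjusted p = 0.986). B2M at 2.32 ± 0.31 and OAS2 at 1.47 ± 0.33 rose among 9 interferon and antigen presentation genes (adjusted p = 0.280), and SOD2 at 0.96 ± 0.0941 among 5 inflammation genes (adjusted p = 0.401). Growth factor genes had 1 raised, IGFBP7, and 2 fallen of 13 (adjusted p = 0.660), and tumour suppressors and oncogenes 1 raised of 9 (adjusted p = 0.579). Of 16 hypoxia genes 3 fell (adjusted p = 0.248), of 16 glycolysis genes 1 fell (adjusted p = 0.726) and of 16 DNA replication genes 1 fell (adjusted p = 0.732). The proteasome had 1 raised and 4 fallen of 22 (adjusted p = 0.281), and RNA splicing 2 raised and 1 fallen of 23 (adjusted p = 0.637). Of the other cell types, 1 of 12 leukocyte markers rose, CD3D at 0.46 ± 0.0943 (adjusted p = 0.694), none of 7 endothelial markers was called (adjusted p = 0.992) and 2 of 17 muscle markers fell (adjusted p = 0.221).

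Limma called 910 of 5246 genes (17.3%) between CMT-U229 and CMT-U335, 460 higher and 450 lower in CMT-U229, and 154 of them differed at least 2-fold, 77 in each direction. The sign was the same on all 5 arrays for 891 of them. Averaging the apparent swaps left 410. No other sign pattern gave a called gene, whereas another pattern gave 10 lists against the 5 called here. Adjusted over the list alone, 9 folding genes rose, 5 mesenchymal markers fell, 15 ribosomal genes rose and 3 fell, 3 genes of oxidative phosphorylation rose and 9 fell, and 1 chaperone rose and 7 fell. The count fell to 571 without replicate 5 and to 586 without replicate 2. Of 103 called values of named genes, 28 lost the call when some array was left out, including HSPA5, RPL32, SDHB, SQLE, MSMO1, OAS2 and CD3D, and MSMO1 also lost it with a dye term. With the swaps averaged 36 lost it, these among them, and also CALR and CDKN1A. The ribosomal list lost its call without replicate 5, oxidative phosphorylation without replicate 4 and the chaperones without replicate 2, 3 or 4 and with the swaps averaged (adjusted p = 0.0554). In all 3 pairs together, median, mean and test of a list differed in sign in 20 of 93 list tests and in none of the 19 called.

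**Figure D2:**
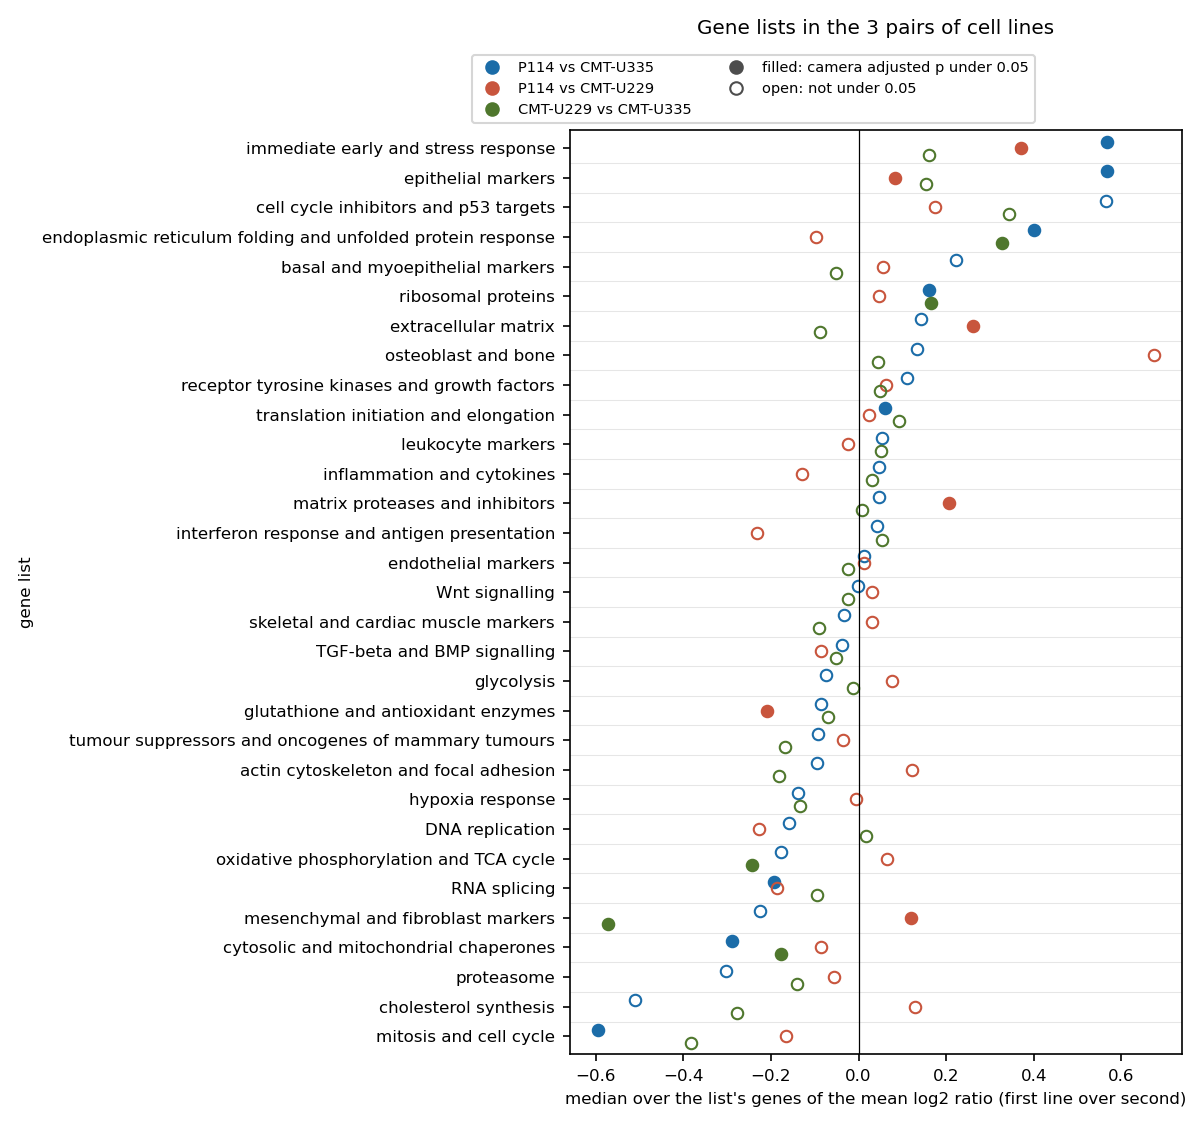
Median log2 ratio over the measured genes of each list, for each pair of lines (1 point per pair; filled where camera's adjusted p lay under 0.05 with its preset correlation). There are 19 filled points among 93; with an estimated correlation none would be filled.

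Genes known from mammary tumours that were to be named whatever their values were not called as genes. The growth factor receptor ERBB2 was at 0.02 ± 0.0965 in P114 over CMT-U335 (adjusted p = 0.930, limma), 0.04 ± 0.0892 in P114 over CMT-U229 (adjusted p = 0.894) and 0.05 ± 0.0950 in CMT-U229 over CMT-U335 (adjusted p = 0.796). EGFR was at 0.25 ± 0.0970, 0.32 ± 0.13 and 0.04 ± 0.12 in the same order. The mesenchymal filament gene VIM was at -0.33 ± 0.11, -0.04 ± 0.11 and -0.57 ± 0.16, with adjusted p = 0.0520 in the last pair. Tested singly, 1 of its 3 probes was called lower in P114 than in CMT-U335, at -0.47 (adjusted p = 0.0390). MET was not among the named probes.

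Lists with under 5 measured genes were not tested by camera. Of 4 hormone receptor and milk genes, GHR, the growth hormone receptor, fell in P114 against CMT-U229 (-0.57 ± 0.0998, limma adjusted p = 0.0172) and rose in CMT-U229 against CMT-U335 (0.81 ± 0.0723, adjusted p = 0.000680). In P114 over CMT-U335 GHR was at 0.16 ± 0.10 and not called. Of its 13 probes tested singly 1 was called lower, at -0.38 (limma, adjusted p = 0.0463), and 0 higher. These 13 probes are repeated spots of the same sequence, with an SD within an array of 0.255 at the median and 0.63 at most. Of 4 Notch genes, RBPJ, the nuclear effector of the pathway, rose in P114 (0.42 ± 0.11) and in CMT-U229 (0.44 ± 0.0807) over CMT-U335. Of 4 adipocyte markers, the lipase PNPLA2 rose in CMT-U229 over CMT-U335 (0.58 ± 0.15). The cartilage genes COL2A1 and COMP were not called in any pair. The calls of GHR in P114 against CMT-U229, of RBPJ in P114 over CMT-U335 and of PNPLA2 were lost when some array was left out, and that of RBPJ also with a dye term. With the apparent swaps averaged, that of GHR in P114 against CMT-U229 and both of RBPJ were lost.

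Genes that differed between a line and both others were then collected. CMT-U335 was set apart by 535 genes, 325 higher and 210 lower than in both other lines. The strongest were the protease CTSK, higher by 3.29 ± 0.25 on the log2 scale over P114 and by 3.98 ± 0.23 over CMT-U229, and PROS1, higher by 3.36 ± 0.16 and 3.26 ± 0.12. SPTAN1, TFPI2 and PLS3 followed among the higher genes. Lower in CMT-U335 were IGFBP7 (-2.59 ± 0.15 and -3.34 ± 0.13), SPP1 (-4.12 ± 0.18 and -2.58 ± 0.34), MT2A (-3.22 ± 0.0915 and -2.53 ± 0.22), KRT8 (-2.46 ± 0.20 and -2.56 ± 0.23) and CHD1L (-2.37 ± 0.30 and -3.40 ± 0.0906). P114 was set apart by 209 genes, 108 higher and 101 lower. TMEFF2, STEAP1, ACSL5, KRT18 and NDUFV2 led the higher ones, and FABP5 (-2.15 ± 0.17 against CMT-U335 and -3.76 ± 0.22 against CMT-U229), ALDH1L2, LOC480844, ARMCX3 and the small heat shock protein gene CRYAB (-1.79 ± 0.16 and -1.70 ± 0.18) the lower ones.

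CMT-U229 was set apart by 146 genes, 91 higher and 55 lower. MGST1 was higher by 4.61 ± 0.17 over P114 and by 4.52 ± 0.22 over CMT-U335, and RGCC, MYLK, FGL2 (1.98 ± 0.28 and 2.41 ± 0.20) and CLU (1.97 ± 0.17 and 2.92 ± 0.12) followed. Lower were COL1A2 (-2.06 ± 0.30 and -3.39 ± 0.22), CMBL (-1.66 ± 0.0806 and -1.54 ± 0.24), S100A4 (-1.54 ± 0.0842 and -1.58 ± 0.19), TACC2 (-1.41 ± 0.0925 and -1.30 ± 0.10) and the matricellular gene CCN1 (-1.29 ± 0.21 and -2.33 ± 0.20). Independent lists of the same lengths would share 64.8 higher and 36.3 lower genes for CMT-U335, 13.7 and 30.1 for P114, and 18.3 and 14.9 for CMT-U229. Both pairs of a line contain that line, so their ratios are not independent. An overlap above these numbers is built in and shows nothing by itself. The pairs used different arrays. With the apparent dye swaps averaged, 263 genes were set apart in CMT-U335, 50 in P114 and 27 in CMT-U229, and SPTAN1, ARMCX3, LOC480844, CRYAB, FGL2, COL1A2, CMBL and CCN1 were no longer among them. Where pairs shared RNA of the common line, part of the overlap may come from it. The P114 count fell to 116 and the CMT-U229 count to 89 without replicate 1 of P114 against CMT-U229. Without replicate 2, 3 or 5 of that pair the P114 count was 127, 138 or 132.

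**Figure D3:**
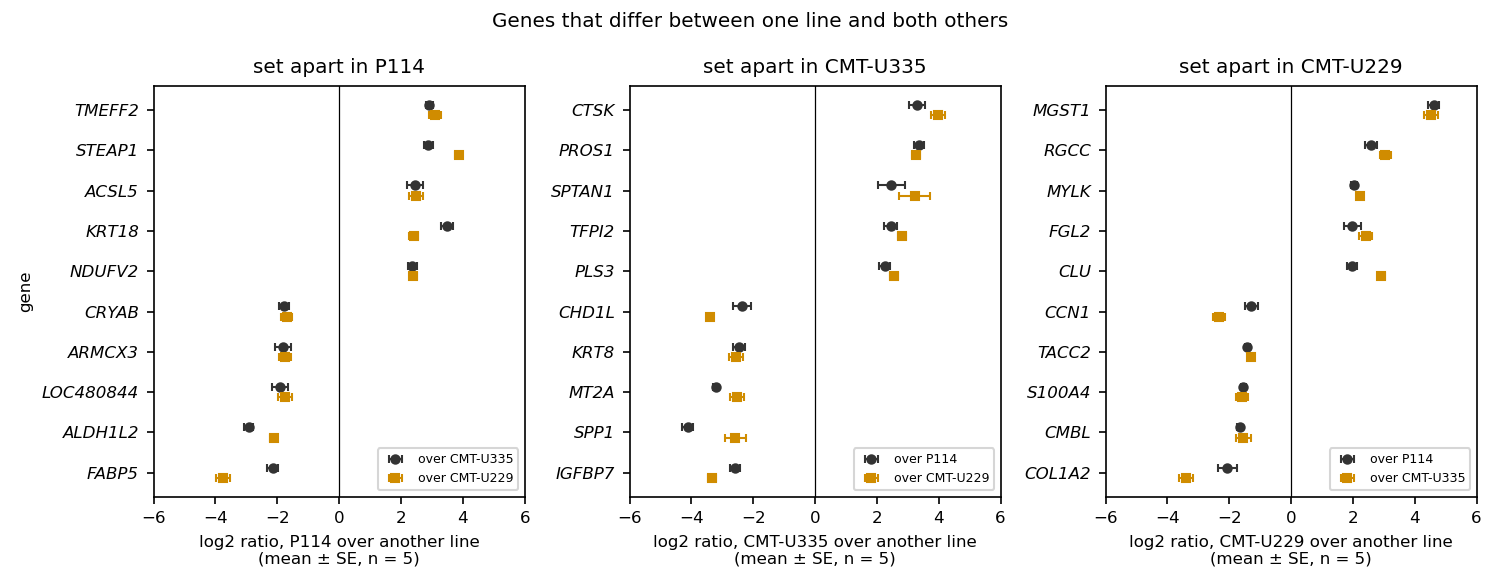
Log2 ratio of a line over each of the other lines (mean ± SE, n = 5 arrays each) for the 5 genes with the largest ratios in each direction among the genes set apart in that line. MGST1 in CMT-U229 lies at 4.61 and 4.52, and SPP1 in CMT-U335 at -4.12 and -2.58.

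The closed loop allowed the direct ratio of P114 over CMT-U335 to be compared with the indirect ratio through CMT-U229. Across 5245 genes, which are not independent replicates, the direct and indirect ratios correlated at 0.887 (Spearman 0.800). Of the 1169 genes called directly, 1162 had the same sign on the indirect path. In limma 0 genes differed between the paths after adjustment, and 17 did at an unadjusted p under 0.05, where 262.2 would do so by chance. So few show that the error in this comparison was set too wide, and small failures would be missed. When the direct arrays of 200 genes were shifted by a log2 ratio of 0.5, 1 or 2, the test found 0, 156 and 191 of them. This compared whether labels, direction and scaling match between arrays. It would come out the same with every ratio turned, so it does not settle the direction, and it does not compare the amount of RNA.

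**Figure D4:**
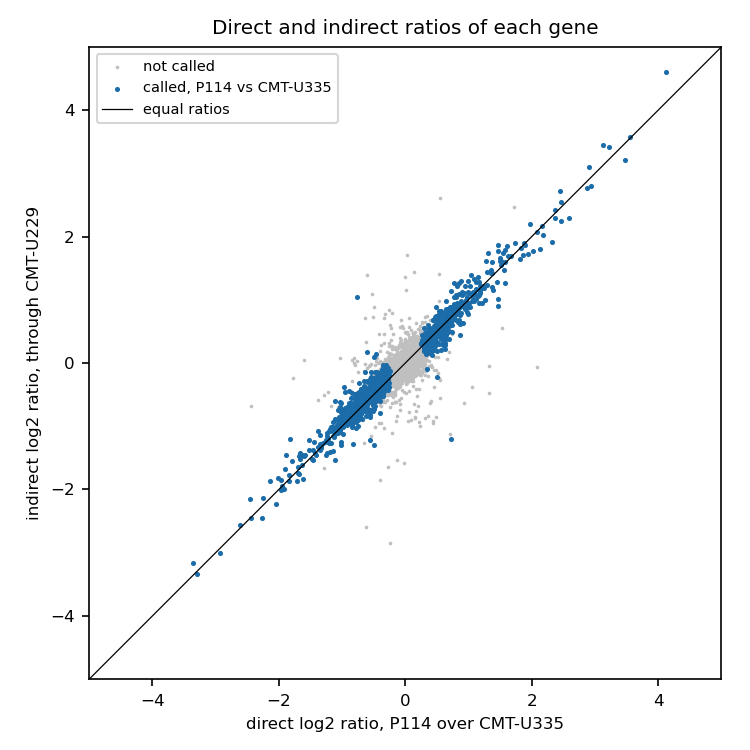
Indirect log2 ratio of P114 over CMT-U335 through CMT-U229 (vertical axis) against the direct log2 ratio (horizontal axis), with 1 point per gene for 5245 genes. The 1169 genes called directly (blue) lie along the line of equal ratios, 1162 of them with the same sign on both axes.

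The size of the ratios was compared between pairs with the array as the unit. The median absolute log2 ratio over genes was 0.223 ± 0.0370 (SD, n = 5 arrays) for P114 against CMT-U335. It was 0.193 ± 0.0305 for P114 against CMT-U229 and 0.206 ± 0.0313 for CMT-U229 against CMT-U335. The differences were 0.0305 (exact two-sided permutation p = 0.190), 0.0175 between the pairs with CMT-U335 (exact permutation p = 0.413) and 0.0130 (exact permutation p = 0.540), and all 3 had an adjusted p of 0.540. None was larger than the spread between arrays. After scale normalization between arrays, which brings their spreads together by construction, the first was 0.00655, the second 0.00812 and the last -0.00157. The smallest p the 5 against 5 arrays allow is 0.00794.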

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

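The tests of why the fewest genes were called between P114 and CMT-U229 were chosen only after that result was seen, as was the alternative that sets gene medians to 0. Among 322 values of named genes, 15 (4.66%) had an array far from the other 4, where chance gives 5%, and none of 3 array measures had. In P114 against CMT-U335 these were CCNG1 (1.97 in replicate 4, 1.07 to 1.32 in the others), MSMO1 (0.233 in replicate 2, -1.38 to -0.956), B2M (1.49 in replicate 2, 0.275 to 0.541), SCD (0.538 in replicate 2, -0.665 to -0.349), DUSP1 (0.679 in replicate 2, 1.63 to 1.97) and XBP1 (1.42 in replicate 4, 0.575 to 0.809). In P114 against CMT-U229 they were MGST1 (-5.40 in replicate 3, -4.50 to -4.21), EFEMP1 (-0.906 in replicate 4, -2.03 to -1.71), CDKN1A (0.210 in replicate 4, 1.98 to 2.52), CDKN2C (-0.0999 in replicate 4, -1.70 to -1.37) and TCP1 (0.716 in replicate 1, -2.28 to -1.56). In CMT-U229 against CMT-U335 they were PROS1 (-2.74 in replicate 4, -3.44 to -3.27), COMP (-1.08 in replicate 3, -0.106 to 0.151), ID3 (0.0254 in replicate 4, 0.372 to 0.45) and OAS2 (3.10 in replicate 1, 0.784 to 1.38). The array with the most was replicate 2 of P114 against CMT-U335, with 4.

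Probes without a gene symbol, which no comparison of genes used, were also called when tested as single probes. They numbered 996 of 14482 (6.88%) in P114 against CMT-U335, 341 (2.35%) in P114 against CMT-U229 and 802 (5.54%) in CMT-U229 against CMT-U335. The shares of named probes were 16.8%, 5.37% and 13.3%.

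P114 and CMT-U229 had the fewest called genes, 383 against 1169 and 910. The tables argue against noisier arrays in this pair, since the residual SD of the log2 ratios was 1.01 times the mean of the other pairs. A smaller difference between these lines is a candidate explanation: the SD of log2 ratios shared by the arrays was 0.298, against 0.407 and 0.377, and with any array left out it stayed between 0.286 and 0.310 while the others stayed above. Between arrays of different apparent dye swaps it was 0.292, against 0.402 and 0.374, and at most 0.305 with any swap left out, where the others stayed at 0.351 or more. The permutation test over arrays found no difference in the size of ratios, which include noise, so this stays a hypothesis found and tested on the same data.

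In P114 against CMT-U335, 64.6% of called genes were lower in P114. The tables argue against a dye bias, since the share was 63.5% with a dye term. Centring may account for part of it: with the gene median of each array at 0 the share was 58.8%, 683 lower against 478 higher, which decides neither way. A real surplus of lower genes in P114 stays open and was not tested otherwise.

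Each result of a fit across genes was set against the other sign patterns of its arrays. For the pairs there are 16 patterns, too few for a share under 0.05, and they count apparent dye swaps as separate arrays. The real counts of genes were 1169, 383 and 910 and the highest other was 0 in each pair, so 1 pattern, the real one, gave as many. The real counts of lists were 8, 6 and 5 and the highest other was 10 in each pair, and 2, 9 and 8 of the 16 patterns gave as many. For genes set apart, 209, 535 and 146 in P114, CMT-U335 and CMT-U229, the highest other of 100 patterns drawn was 0, and 1 pattern, the real one, gave as many. As no other pattern of a single pair called a gene, nearly all of these patterns could give only 0, and the comparison decides nothing about chance in the overlap of pairs.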

How the results depend on the processing

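The alternatives that set gene medians to 0, that leave out list members on chromosome 13 and that average apparent dye swaps were chosen after seeing the data. Values are given for P114 against CMT-U335, P114 against CMT-U229 and CMT-U229 against CMT-U335 in this order, and the cause was not tested except where more arrays in a fit, a stricter threshold or more tests explain a count by construction. Genes called numbered 1757, 1056 and 1445 in the loop fit, 1903, 1153 and 1496 in the loop fit with a dye term, 642, 159 and 470 at an adjusted p under 0.01, 195, 93 and 154 with a log2 ratio of at least 1, and 2289, 754 and 1826 probes with each probe tested by itself. In a fit over 15 arrays P114 against CMT-U229 had 650. Leaving out 1 array gave 835 to 1031, 202 to 408 and 571 to 863 genes. With the swaps averaged 839, 79 and 410 genes were called, fewer than with any of 14 other ways to couple the arrays (lowest 849, 156 and 477), and 263, 50 and 27 genes were set apart in CMT-U335, P114 and CMT-U229. Leaving out 1 array keeps the other of its swap. A dye term (1097, 314 and 846), scale normalization and the SAM-type test (1409, 528 and 1081) stayed within 1.5 times.

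Genes set apart in P114, CMT-U335 and CMT-U229 numbered 580, 935 and 418 in the loop fit, 650, 993 and 450 with its dye term, 84, 266 and 55 at an adjusted p under 0.01, and 41, 82 and 35 with a log2 ratio of at least 1. In a fit over 15 arrays P114 had 345 and CMT-U229 242. Leaving out 1 array gave 116 to 233, 380 to 514 and 89 to 142. Lists called numbered 0, 0 and 0 with an estimated correlation, and fry, which does not compare a list with other genes, called 13 in P114 against CMT-U335 and 9 in CMT-U229 against CMT-U335. Leaving out 1 array gave 6 to 10, 7 to 11 and 4 to 8 lists; P114 against CMT-U229 had 10 without replicate 1 and 11 without replicate 4, and CMT-U229 against CMT-U335 had 8 without replicate 3. Of the 19 list calls 18 were kept with a dye term, 16 with scale normalization, 12 with fry, 18 without members on chromosome 13 and 16 with the swaps averaged. Fry lost the ribosomal and translation lists in P114 against CMT-U335 (adjusted p = 0.261 and 0.0775). In P114 against CMT-U229 fry lost the matrix and immediate early lists (adjusted p = 0.0775 and 0.104). In CMT-U229 against CMT-U335 fry lost the ribosomal, oxidative phosphorylation and chaperone lists (adjusted p = 0.22, 0.224 and 0.0972).

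Loop closure failed for 0 genes under each alternative and with each array left out (0 to 0), in a test that missed all planted failures of 0.5, so this says nothing about small ones. The differences in size of ratios lay at 0.0217 to 0.0420 for P114 against CMT-U335 minus P114 against CMT-U229, 0.00873 to 0.0291 for P114 against CMT-U335 minus CMT-U229 against CMT-U335, and 0.00302 to 0.0242 for CMT-U229 against CMT-U335 minus P114 against CMT-U229 with 1 array left out. In the same order they were 0.00655, 0.00812 and -0.00157 after scale normalization, and 0.0719, 0.0248 and 0.0471 with the standard deviation as the measure, where the smallest exact permutation p was 0.0714. With the swaps averaged they were 0.0408, 0.0106 and 0.0302 (smallest exact permutation p = 0.200). Of 279 called values of named genes, 253 stayed called with a dye term, 269 with scale normalization, 256 in a fit over 15 arrays, 274 in the loop fit and 186 with the swaps averaged. For GHR in P114 against CMT-U335, at 0.16 and not called, the probe with the smallest p lay at -0.38 (adjusted p = 0.0463). It was the only one called of 13 repeated spots of the same sequence. Turning the direction exchanges the counts, for example 755 higher and 414 lower in P114 against CMT-U335.

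Deviations of arrays from the mean of their pair were correlated between pairs, to see whether equal replicate numbers went together. Of 15 correlations at equal numbers 3 lay above 0.1, and 2 of 15 arrays correlated best with their own number. Over all 75 combinations of arrays, the deviations also followed the dye order (median correlation 0.15 in its direction, 59 above 0). The check therefore cannot settle whether arrays of equal number shared RNA. With the replicate number as a block, 1172, 515 and 920 genes and 8, 8 and 6 lists were called, and 269, 539 and 197 genes were set apart in P114, CMT-U335 and CMT-U229. Of the calls made without the block, 1030, 347 and 814 genes, 256 of 279 named values and 18 of 19 lists stayed, and the splicing list of P114 against CMT-U335 did not (adjusted p = 0.0851). Signal over background was not known, so what faint spots limit could not be shown.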

Other observations

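The tests on chromosomes were chosen only after the shift of chromosome 13 had been seen, and none was planned before the data were examined. Genes were placed on chromosomes with the RefSeq table, 5002 of them on 39 chromosomes. Of 96 genes of chromosome 13, 45 were higher and 8 lower in P114 than in CMT-U335, with a median log2 ratio of 0.27 (camera, adjusted p = 1.68e-09 over 117 tests; adjusted p = 0.0742 with an estimated correlation), and the median of the chromosome lay above 0 on 5 of 5 arrays. In CMT-U229 over CMT-U335, 39 were higher and 9 lower, with a median of 0.18 (adjusted p = 2.82e-06; adjusted p = 0.0742 with an estimated correlation). Between P114 and CMT-U229, 7 were higher and 3 lower (median 0.07, adjusted p = 0.00178; adjusted p = 0.352 with an estimated correlation). Called genes higher in P114 than in CMT-U335 included RPL30, EIF3E, EIF3H, TRIB1 (1.87), RPL8, TMEM165 (1.87) and IGFBP7 (2.59), and lower ones SQLE (-1.17), NSMCE2 (-1.14), LOC475101 (-1.05) and ARL9 (-1.15), all chosen after their values were seen. In gene order, higher and lower calls formed 11 runs in this pair against a median of 15 in shuffled order (one-sided permutation p = 0.0612). They formed 9 against 16 in CMT-U229 over CMT-U335 (one-sided permutation p = 0.00300) and 6 against 5 in P114 over CMT-U229 (one-sided permutation p = 0.831).

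Other chromosomes moved against CMT-U335 too. Chromosome 33 was lower in P114 (median -0.20, 20 of 53 genes fallen and 2 raised, adjusted p = 0.00587; adjusted p = 0.361 with an estimated correlation) and in CMT-U229 (-0.18, 13 fallen and 2 raised, adjusted p = 0.00193; adjusted p = 0.352 with an estimated correlation). Chromosome 21 was higher in P114 (18 of 111 raised and 2 fallen, adjusted p = 5.59e-06; adjusted p = 0.0742 with an estimated correlation) and in CMT-U229 (23 raised and 6 fallen, adjusted p = 5.13e-05; adjusted p = 0.223 with an estimated correlation). In all, 19 of 117 tests were called with the preset correlation and 0 with an estimated one, and with the apparent dye swaps averaged all 19 stayed. With adjustment within each pair, 8, 3 and 10 chromosomes were called in P114 against CMT-U335, P114 against CMT-U229 and CMT-U229 against CMT-U335, and the highest of the other sign patterns of the arrays gave 8, 4 and 7. For chromosome 13 the unadjusted camera p was 1.43e-11, 0.000137 and 4.82e-08 in the same order. The smallest from another sign pattern was 4.9e-08, 0.000595 and 2.67e-06, so small values also arose with arrays turned.

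Gains or losses of chromosome segments in the lines are a candidate explanation for the shift of chromosome 13, as a hypothesis. If segments of other chromosomes had changed too, neighbouring genes there would move together. Over 4868 pairs of neighbours off chromosome 13 the ratios in P114 over CMT-U335 correlated at 0.103, where the highest of 1000 shuffles gave 0.0407. These pairs hold no gene of chromosome 13, and a change there need not come with others, so they do not decide what shifted it. For the correlation off chromosome 13, tables argue against related neighbours sharing cDNA as the whole cause (0.0872 without related symbols). They also argue against place on the array as its cause (0.104 without neighbours of a shared print block). Neither was tested on chromosome 13 itself. For chromosome 13, they argue against ribosomal and translation genes alone (camera, adjusted p = 1.75e-07 with these 5 genes left out). Another sign pattern of the 5 arrays reached 0.0993 for the neighbours. A pattern with 1 array turned keeps part of a real signal and is no clean comparison. In P114 against CMT-U229, however, another pattern reached 0.0757 where the real one gave 0.0604, more than a kept part would give. The shuffles of gene order therefore do not settle what the correlation of neighbours means. Shared regulation of neighbouring genes stays open, and no measurement of DNA copy number was used here. The estimated correlation ended every call, in a test with few degrees of freedom that cannot tell correlation between genes from low power.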
